A study of Rattus norvegicus with 12 samples.

How the data were processed

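Total RNA of rat testes at embryonic day 16 was measured on 12 Affymetrix rat expression arrays, 2 in each of 6 groups: the control and vinclozolin lineages of the F1, F2 and F3 generations. Per the labels' protocols, founder females received intraperitoneal vinclozolin (100 mg/kg/day), a fungicide whose metabolites block the androgen receptor, or a vehicle of sesame oil and DMSO, on days 8 to 14 of pregnancy. Per the same protocols, each RNA came from a pool of about 10 testes of 1 treatment, was extracted with Trizol and was labelled with biotin for standard Affymetrix hybridisation. The arrays of a group were read as replicate pools, so that each p-value measured the spread between RNA pools and not between animals or litters. The labels did not say whether the pools of a group came from different litters, nor on which days the arrays were hybridised.

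The deposited values were linear signal intensity per probe set, running from 0 to 9534.9, with 33 values equal to 0. The 2% trimmed mean was the same, near 125.03, on every array, so a global scaling had been applied before deposit. The software and version of that summarisation were not given in the sources used here, and no detection calls were used. Of 31099 probe sets, 57 were Affymetrix controls. They were left out of the tests and used as measures of RNA quality: the signal of the 5' and middle probe sets of beta-actin and of the 5' probe set of Gapdh was divided by that of the 3' probe set. The spike-in control probe sets were summarised by their geometric mean.

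Values were transformed as log2(value + 16), which shrinks the fold changes of dim probe sets, so fold changes of such genes are understated. The array medians on that scale spanned 0.157, under the limit of 0.5 above which quantile normalization would have been the main setting, and the values were used as deposited. The 9313 probe sets in the lowest 30% of mean log2 value (below a signal of 14.8) were left out, and 21729 were tested. A linear model with 6 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with 6 residual and 8.97 prior degrees of freedom. A Benjamini-Hochberg adjusted p under 0.05 was called. The contrasts were vinclozolin minus control in each generation, the mean of the 3 differences, the dependence of the difference on generation (F test) and the differences among the 3 control groups (F test). A looser threshold, an unadjusted p under 0.05 with a fold change of at least 1.5, was used for probe sets past it in all 3 generations. With 2 arrays against 2, an exact 2-sided permutation test cannot go below p = 0.333, so the tests of single generations rest on the spread pooled over the 6 groups.

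Probe sets were given gene symbols from the array annotation: 20837 had 1 symbol, 425 had several and 9780 had none. Of 20832 gene identifiers, 20764 were found in the current rat gene table, and no symbol had changed. Gene groups were 28 lists fixed from textbook knowledge of fetal testis, of tissues that could be carried along in dissection and of an anti-androgen. The 26 lists with at least 5 tested genes were tested with limma's camera on the brightest probe set of each of 11293 genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Each call was also tested with an estimated correlation. Member counts used the threshold over all tested probe sets, and counts adjusted over the list alone are given beside them.

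The genes named were set by rule: for each generation, the 10 highest and 10 lowest fold changes among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between lineages; for the mean, the 10 highest and lowest among called probe sets with 1 sign in all 3 generations; for the looser threshold, up to 10 per direction; for each list, up to 4 called members by size of change, or else the 2 with the smallest p; for both F tests, the 5 smallest p. Other genes named were picked after their values were seen, as the text states. Where a gene had several probe sets, the value is that of the probe set the rule picked, and other probe sets of the gene are given beside it for some genes only. The design, lists, thresholds and naming rule were fixed before the data were examined, as were the alternatives, except for 3 kinds. Cyclic loess normalization, the beta-actin ratio as a covariate and leaving a generation out of the mean were chosen after seeing the data.

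The code was tested on simulated data with 200 changed probe sets among 21729. With 2 arrays against 2, 37.3% of 1.5-fold, 77.6% of 2-fold and 98.5% of 4-fold changes were recovered, and 11 unchanged probe sets were called. With 6 against 6 the recovered shares were 73.1%, 100% and 100%, with 11 unchanged probe sets called. A list of 63 genes shifted by 0.2 was called and 0 of 25 other lists were. The simulated noise was drawn independently for each probe set, so it held no correlation between genes. False list calls under such correlation were therefore not gauged by the simulation. The simulated spread of a probe set was also the same in all 6 groups. Real replicates differed by a pooled SD of 0.130 in F3 controls and 0.244 in F1 vinclozolin arrays. Recovery and false calls at the spread of the F1 vinclozolin arrays were thus not gauged either. The alternatives tried were other scalings, filters, offsets, variance models, array weights, replicate terms, thresholds, 1 probe set per gene and leaving out each array in turn. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision.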

Results

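Testes of male rat embryos at day 16 of gestation were compared between a control and a vinclozolin lineage in 3 successive generations. Embryos of F1 were in the womb when the founder females were dosed on pregnancy days 8 to 14. F2 and F3 embryos descended from them without further dosing in the protocols. Each of the 6 groups had 2 arrays, each from a pool of about 10 testes. Array medians lay between a signal of 44.5 and 47.1 on control arrays and between 40.5 and 42.8 on vinclozolin arrays. On the log2 scale the medians differed by −0.0952 on average, vinclozolin minus control (exact permutation test, 2-sided p = 0.00216, 0.00361 adjusted over 5 measures). The protocols of the F2 and F3 vinclozolin groups describe the mated animals as coming from different control lines, and the group names in the titles were followed. The Y-linked genes Uty (1383720_at) and Eif2s3y were detected on all 12 arrays, at signals of 154 to 248 and 420 to 876. Xist, expressed from the inactive X chromosome, gave at most 17.1 on its 4 probe sets, and Sry, the testis-determining gene, 4.6 to 12.7.

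Signs of RNA quality moved with lineage. The ratio of 5' to 3' signal of beta-actin was 0.453 ± 0.018 (SD, n = 6) on control arrays and 0.260 ± 0.097 (SD, n = 6) on vinclozolin arrays. The exact permutation test gave p = 0.00216 (2-sided, 924 splits, the smallest p possible; 0.00361 adjusted over 5 measures). The vinclozolin arrays gave 0.171 ± 0.030 in F1, 0.233 ± 0.020 in F2 and 0.378 ± 0.025 in F3 (SD, n = 2 each). The splits of the permutation tests ignored generation and took all 12 arrays as independent. Arrays of 1 vinclozolin group lay closer together than the 6 vinclozolin arrays did, so these p-values may be too small. The Gapdh ratio was 0.986 ± 0.022 on control arrays (SD, n = 6), and 0.684 ± 0.047, 0.760 ± 0.056 and 0.996 ± 0.038 on the F1, F2 and F3 vinclozolin arrays (SD, n = 2 each; exact permutation p = 0.0411 over all 12 arrays, 2-sided, adjusted 0.0411). Replicates differed by a pooled SD of 0.13 to 0.16 on the log2 scale in control groups and of 0.24, 0.20 and 0.18 in the F1, F2 and F3 vinclozolin groups.

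**Figure D1:**
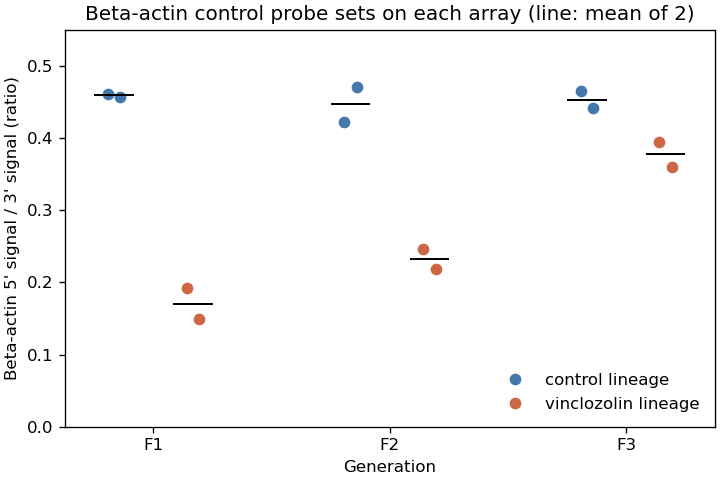
Ratio of the 5' to the 3' probe set signal of beta-actin on each array, by generation and lineage, with each point 1 array and each line the mean of 2. Control arrays lie between 0.423 and 0.471, and vinclozolin arrays between 0.149 and 0.395.

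The F1 comparison asked how embryos of dosed mothers differed from embryos of mothers given vehicle. Fos (1375043_at), an immediate early transcription factor, rose by 2.57 ± 0.29 (log2 fold change ± SE, n = 2 arrays per group, as for all genes below; adjusted p = 2.94e-05). Its relatives in rapid response, Fosb and Ier2, rose by 1.81 ± 0.35 and 1.29 ± 0.15. Ahsp, the chaperone of free alpha-globin, rose by 1.41 ± 0.16, Pi16 by 1.52 ± 0.21 and Lmbr1l by 1.28 ± 0.21. Mbp (1368810_a_at), myelin basic protein, rose by 2.40 ± 0.29, Tpm3 (1387617_at), a tropomyosin, by 1.56 ± 0.17, Tiparp, a target of the aryl hydrocarbon receptor, by 1.38 ± 0.26 and Atp2b1, a calcium pump, by 1.30 ± 0.14. These 4 genes had other probe sets that did not rise: 1383479_at of Mbp gave −0.40, 1398303_s_at of Tpm3 fell by 1.88 and 5 more of its probe sets fell too, and the others of Atp2b1 and Tiparp lay between −0.03 and 0.17.

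The lowest values in F1 were those of Nedd4 (1395157_at), a ubiquitin ligase, which fell by 3.32 ± 0.12 (adjusted p = 6.25e-10), and Eprs1 (1382040_at), a tRNA synthetase, which fell by 2.94 ± 0.19. Falls followed in Ipo5, an importin (−2.50 ± 0.21), Scd2, a fatty acid desaturase (−2.40 ± 0.23), Usp8, a deubiquitinase (−2.34 ± 0.25), Reep6 (−2.31 ± 0.16), and in Caprin1, Cbfb, Ddx3x and Ubap2 (−2.21 to −2.19). Other probe sets of these genes shared some of the falls. Of the 5 others of Nedd4, 4 fell (−1.93 to −0.33) and 1375119_at gave 0.09 (adjusted p = 0.430). Caprin1 also fell at 1395412_at (−1.63) and 1371939_at (−0.31) but not at 1371938_at (0.08), Reep6 at 1372841_at (−0.98) and Scd2 at 1 of 3 others (1367668_a_at, −0.47). The others of Eprs1, Cbfb, Ddx3x and Ubap2 lay between −0.17 and 0.16 and were not called, nor was that of Ipo5 (−0.29), and Usp8 rose at 1390027_at (0.27; adjusted p = 0.0427). Over all 4488 pairs of probe sets of 1 gene, 424 had both members called in F1, of which 169 (39.9%) went in opposite directions, against 47.9% if the directions were independent.

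By gene group, subunits of mitochondrial oxidative phosphorylation were higher in F1 in 40 of 63 tested members and lower in 0 (47 adjusted over the list alone; median 0.33; adjusted p = 8.55e-14, and adjusted p = 0.422 with an estimated correlation). Examples are Ndufa7 (0.92 ± 0.19), Atp5f1e (0.83 ± 0.12) and Ndufb5 (0.82 ± 0.12). Ribosomal protein genes were higher in 31 of 42 and lower in 0 (38 adjusted over the list alone; median 0.31; adjusted p = 1.72e-13, and adjusted p = 0.422 with an estimated correlation), among them Rpl35 (0.50 ± 0.09) and Rps3 (0.43 ± 0.08). After quantile normalization the ribosomal list was no longer called (median 0.06, adjusted p = 0.384). Erythroid genes were higher in 6 of 16 (8 higher and 1 lower adjusted over the list alone; median 0.28; adjusted p = 0.00947, and adjusted p = 0.422 with an estimated correlation), with Hbe2 at 0.86 ± 0.24 and Hbz, an embryonic globin, at 0.72 ± 0.16 beside Ahsp.

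Germ cell genes were lower in 4 of 15 and higher in 0 in F1 (1 higher and 4 lower adjusted over the list alone; median −0.20; adjusted p = 0.0201, and adjusted p = 0.422 with an estimated correlation). The 4 were Kit, the receptor for stem cell factor (−1.86 ± 0.26), Dmrt1, a regulator of testis and germ cell fate (−1.29 ± 0.14), Sox2, a pluripotency factor (1379942_at, −0.95 ± 0.22), and Mov10l1, which acts in the piRNA pathway (−0.74 ± 0.21). Regulators of DNA methylation and chromatin were lower in 10 of 36 and higher in 2 (12 and 3 adjusted over the list alone; median −0.14; adjusted p = 0.0275, and adjusted p = 0.422 with an estimated correlation). Among the lower were the methyltransferase genes Dnmt3a (−1.08 ± 0.19) and Dnmt3b (−0.97 ± 0.30), Uhrf1, whose product recruits the maintenance methyltransferase (−1.08 ± 0.14), and the dioxygenase gene Tet3 (−0.73 ± 0.14). Both probe sets of Dnmt3a fell. Without F1 vinclozolin replicate 2 the germ cell, erythroid and chromatin lists were no longer called (adjusted p = 0.0569, 0.0678 and 0.0569), and without F1 control replicate 1 the chromatin list was not (adjusted p = 0.0702). On the same arrays the beta-actin ratio was 0.171 ± 0.030 (vinclozolin) against 0.459 ± 0.003 (control; SD, n = 2 each).

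Fetal Leydig cell genes had 4 of 20 members higher and 4 lower in F1 (4 and 6 adjusted over the list alone) and were not called as a list (adjusted p = 0.649): Prlr, the prolactin receptor, and Hsd17b3, which makes testosterone, rose by 0.54 ± 0.15 and 0.45 ± 0.11, and Por, the electron donor of steroidogenic P450 enzymes, fell by 0.71 ± 0.14. Prlr had another probe set, 1370789_a_at, that fell by 1.06. Sertoli cell genes had 3 of 16 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.649), with Ptgds, prostaglandin D synthase, at 1.15 ± 0.31. Immediate early and heat shock genes, which include Fos, Fosb and Ier2, had 5 of 29 higher and 3 lower (5 and 4 over the list alone; median −0.03; adjusted p = 0.900). Cell cycle genes had 8 of 41 higher and 4 lower (8 and 4 over the list alone; adjusted p = 0.602). Steroid receptors and androgen-responsive genes had 2 of 15 higher and 1 lower (1 and 1 over the list alone; adjusted p = 0.649). Interstitial and extracellular matrix genes, not called in F1 (adjusted p = 0.144 and 0.148), were called lower after quantile normalization (both adjusted p = 0.0202). With an estimated correlation these gave adjusted p = 0.216 and 0.538.

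In total 5026 of 21729 probe sets (23.1%) were called in F1, 2045 higher and 2981 lower. They covered 3304 of 11293 genes, and 39 were over 2-fold higher and 693 over 2-fold lower. The balance of directions depended on choices: median centring gave 3678 higher and 2199 lower, and 1 probe set per gene gave 1217 higher and 973 lower. Leaving out F1 control replicate 1 or 2 gave 2749 or 2514. Array weights gave 3319 and the 4 F1 arrays alone 2294.

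The F2 comparison asked whether the grandchildren of dosed females, embryos not in the womb at dosing, differed from their own controls. Fos rose by 1.83 ± 0.29 (adjusted p = 8.70e-04), Ergic1, which cycles between endoplasmic reticulum and Golgi, by 1.34 ± 0.13 (adjusted p = 2.40e-05) and Psap, the precursor of the lysosomal saposins, by 1.09 ± 0.10. Scgb1d4, a secretoglobin and subunit of prostatein, rose by 1.15 ± 0.19, from a control signal of 0.85 to 21.3. Cd99 (1381867_at) rose by 1.34 ± 0.36, Dok3 by 1.23 ± 0.20, Fosb by 1.16 ± 0.35, Gcnt3 by 1.13 ± 0.20, the ribosomal gene Rpl39 by 1.12 ± 0.31 and the metallothionein Mt3 by 1.11 ± 0.19. The other probe set of Cd99, 1371918_at, gave −0.35.

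Nedd4 (1395157_at) and Eprs1 (1382040_at) again had the lowest values in F2, with falls of −2.81 ± 0.12 (adjusted p = 7.14e-09) and −2.61 ± 0.19. Next were the splicing factor genes Sf3b1 (−2.28 ± 0.17) and Scaf11 (−2.15 ± 0.21), the RNA-binding protein gene Elavl2 (−2.09 ± 0.19) and the helicase gene Dhx36 (−2.05 ± 0.16). Ppp3r1, a calcineurin subunit, stood at −2.05 ± 0.21, Ccar1 at −2.05 ± 0.20, the pseudogene Ddx3x-ps1 at −1.94 ± 0.18 and Cbfb at −1.76 ± 0.22. Ccar1 fell at another probe set (1382238_at, −0.61) and rose at 1376864_at (0.43; adjusted p = 0.0278). Falls were shared by 1389840_at of Sf3b1 (−0.67), 1374154_at and 1376049_at of Scaf11 (−0.53 and −0.42) and 1379101_at of Dhx36 (−0.47). Not called were 1390234_at of Sf3b1 (−0.14), 1397528_at of Scaf11 (0.35), 1393432_a_at of Dhx36 (0.05), 1383736_at of Elavl2 (0.01) and 1399033_at of Cbfb (0.06). Of 198 pairs of probe sets of 1 gene with both called in F2, 81 (40.9%) went in opposite directions, against 45.2% if independent.

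Oxidative phosphorylation genes were higher in 19 of 63 members in F2 and lower in 0 (21 adjusted over the list alone; median 0.23; adjusted p = 2.14e-07, and adjusted p = 0.738 with an estimated correlation), with Atp5f1e at 0.58 ± 0.12 and Ndufb3 at 0.50 ± 0.10. Ribosomal protein genes were higher in 7 of 42 and lower in 0 (13 adjusted over the list alone; median 0.16; adjusted p = 6.12e-05, and adjusted p = 0.789 with an estimated correlation). This call was lost after quantile normalization (adjusted p = 0.601) and cyclic loess (adjusted p = 0.277, chosen after seeing the data). Genes of interstitial progenitors and stroma were lower in 6 of 16 and higher in 3 (8 and 3 adjusted over the list alone; median −0.22; adjusted p = 0.00683, and adjusted p = 0.319 with an estimated correlation). The lower members included Wnt5a, a non-canonical Wnt ligand (−0.95 ± 0.14), the growth factor gene Ptn (−0.65 ± 0.13) and the proteoglycan gene Dcn (−0.58 ± 0.13). Igf1 (1370333_a_at) rose by 0.40 ± 0.11, while another of its probe sets, 1382599_at, changed by −0.91. On the same arrays the beta-actin ratio was 0.233 ± 0.020 (vinclozolin) against 0.447 ± 0.034 (control; SD, n = 2 each).

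Leydig cell genes were higher in 4 of 20 members in F2 and lower in 1, also over the list alone, and were not called as a list (adjusted p = 0.205). Hsd17b3 rose by 0.50 ± 0.11, Star (1368406_at), which moves cholesterol into mitochondria, by 0.49 ± 0.09, Inhba, an activin subunit, by 0.48 ± 0.13 and the Leydig hormone gene Insl3 by 0.45 ± 0.08. A different probe set of Star, 1387174_a_at, changed by −0.51. Germ cell genes were lower in 3 of 15 and higher in 0, also over the list alone (adjusted p = 0.205), with Kit at −1.02 ± 0.26. Chromatin regulators were lower in 6 of 36 and higher in 2 (6 and 4 over the list alone; adjusted p = 0.205), with Uhrf1 at −0.79 ± 0.14 and Ehmt1, a histone methyltransferase gene, at −0.54 ± 0.09. That list was called lower after quantile normalization (adjusted p = 0.0483, and adjusted p = 0.570 with an estimated correlation). Also not called in F2, with the same counts over the list alone, were erythroid genes (2 of 16 higher and 0 lower, median 0.00, adjusted p = 0.754), immediate early and heat shock genes (4 of 29 and 0, median −0.01, adjusted p = 0.754), extracellular matrix genes (3 of 47 and 4, adjusted p = 0.954), Sertoli cell genes (1 of 16 and 0, adjusted p = 0.4996) and androgen-responsive genes (2 of 15 and 1, adjusted p = 0.952).

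In total 3118 probe sets (14.3%, 2093 genes) were called in F2, 1021 higher and 2097 lower, and 21 were over 2-fold higher and 416 over 2-fold lower. Median centring turned the balance, with 2594 higher and 1494 lower, and 1 probe set per gene gave 1072 calls, 575 higher and 497 lower. The count was 1157 and 1212 without F2 control replicates 1 and 2, 1083 without F2 vinclozolin replicate 2, and 4884 and 4883 without F1 vinclozolin replicates 1 and 2, which entered only through the pooled spread.

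The F3 comparison asked whether great-grandchildren of the dosed females still differed from controls. The highest values were 3 secretoglobins whose products form prostatein, the main secretion of the rat ventral prostate: Scgb1d4 rose by 4.08 ± 0.19 (adjusted p = 3.17e-08), Scgb1d2 by 3.65 ± 0.22 (adjusted p = 3.03e-07) and Scgb2a1 by 3.45 ± 0.27 (adjusted p = 7.27e-06). Their mean signals went from 0.50, 3.45 and 2.80 on control arrays to 263, 228 and 190. Immediate early genes came next: Fos rose by 3.07 ± 0.29 (adjusted p = 6.44e-05), Fosb by 1.62 ± 0.35, Egr1 by 1.46 ± 0.17 and Ier2 by 1.42 ± 0.15. Hba-a3, an alpha-globin, rose by 1.06 ± 0.14, Ahsp by 1.05 ± 0.16 and the cytokine gene Il23a by 1.05 ± 0.27.

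**Figure D2:**
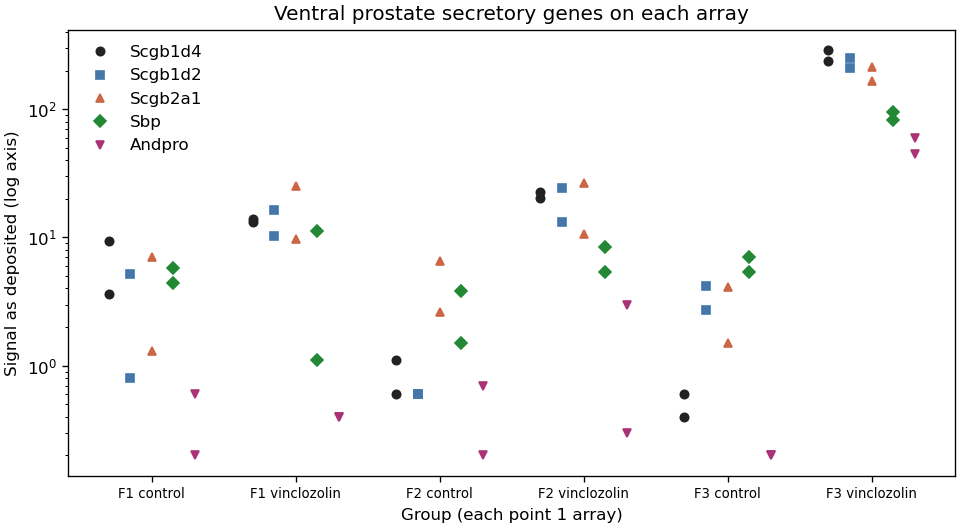
Signal of the secretory genes of the rat ventral prostate on each of the 12 arrays, on a log axis, with each point 1 array. Scgb1d4, Scgb1d2, Scgb2a1 and Sbp reach 82 to 288 on both F3 vinclozolin arrays and at most 26.4 on the other 10.

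The lowest values in F3 were those of Tbl1x (1379469_at), a corepressor subunit, which fell by 1.75 ± 0.31, Scaf11 (−1.61 ± 0.21), Sox2 (1381874_at, −1.49 ± 0.28), Cntnap1 (−1.47 ± 0.33), Plpp3 (−1.42 ± 0.29) and Tjp3, a tight junction protein (−1.38 ± 0.20). Ring1, a Polycomb protein, F8, coagulation factor VIII, Eprs1 and Zfpm1, a cofactor of GATA factors, changed by −1.35 ± 0.28, −1.33 ± 0.28, −1.29 ± 0.19 and −1.28 ± 0.20. The probe set 1388478_at of Tbl1x gave −0.00 and 1379942_at of Sox2 gave −0.01. Of 24 pairs of probe sets of 1 gene with both called in F3, 4 (16.7%) went in opposite directions, against 28.1% if independent.

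Ribosomal protein genes were higher in 11 of 42 members in F3 and lower in 0 (30 adjusted over the list alone; median 0.28; adjusted p = 1.32e-18, and adjusted p = 0.350 with an estimated correlation), with Rps6 at 0.40 ± 0.09. After quantile normalization that list was not called (median 0.02, adjusted p = 0.894). Oxidative phosphorylation genes were higher in 6 of 63 and lower in 0 (12 adjusted over the list alone; median 0.21; adjusted p = 4.07e-13, and adjusted p = 0.366 with an estimated correlation), with Sdhc at 0.46 ± 0.09. Erythroid genes were higher in 6 of 16 and lower in 0 (8 adjusted over the list alone; median 0.34; adjusted p = 1.71e-07, and adjusted p = 0.350 with an estimated correlation), with Hbg1 at 0.80 ± 0.19 and Hbb at 0.62 ± 0.10. Immediate early and heat shock genes were higher in 7 of 29 and lower in 0 (10 and 2 adjusted over the list alone; median 0.13; adjusted p = 2.16e-04, and adjusted p = 0.350 with an estimated correlation). All 7 were immediate early genes: the 4 named above and, picked after their values were seen, Dusp1, Jun and Jund at 0.91, 0.54 and 0.34.

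Extracellular matrix genes were lower in 7 of 47 members in F3 and higher in 0 (12 and 1 adjusted over the list alone; median −0.13; adjusted p = 1.28e-04, and adjusted p = 0.350 with an estimated correlation). They included the genes of perlecan (Hspg2, −0.69 ± 0.15), a laminin chain (Lamb2, −0.60 ± 0.11), a collagen crosslinker (Loxl2, −0.58 ± 0.13) and a fibrillin (Fbn2, −0.57 ± 0.10). Fetal Leydig cell genes were higher in 4 of 20 and lower in 0 (6 and 1 adjusted over the list alone; median 0.15; adjusted p = 0.0131, and adjusted p = 0.350 with an estimated correlation). Prlr rose by 0.66 ± 0.15, Hsd17b3 by 0.54 ± 0.11, Star by 0.48 ± 0.09 and Insl3 by 0.39 ± 0.08. The Leydig list was not called after quantile normalization (adjusted p = 0.0568) or cyclic loess (adjusted p = 0.0816), nor without F3 vinclozolin replicate 1 (adjusted p = 0.232). On the same arrays the beta-actin ratio was 0.378 ± 0.025 (vinclozolin) against 0.453 ± 0.016 (control; SD, n = 2 each). Germ cell genes were lower in 1 of 15 (Sall4, −0.79 ± 0.15; also 1 over the list alone; adjusted p = 0.672). Androgen-responsive genes were higher in 2 of 15 and lower in 1, also over the list alone (adjusted p = 0.951, direction up, with a median of −0.08). Sertoli cell genes were higher in 1 of 16 and lower in 0 (1 and 1 over the list alone; adjusted p = 0.458) and interstitial genes lower in 1 of 16 and higher in 0, also over the list alone (adjusted p = 0.280).

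In total 676 probe sets (3.11%, 475 genes) were called in F3, 228 higher and 448 lower, and 19 were over 2-fold higher and 57 over 2-fold lower. The count was 67 and 65 without F3 control replicates 1 and 2, 213 and 147 without F3 vinclozolin replicates 1 and 2, 393 and 398 without F1 control replicates 1 and 2, 405 and 404 without F2 control replicates 1 and 2, and 2172 and 2170 without F1 vinclozolin replicates 1 and 2. It was 2712 with array weights, 2262 from the 4 F3 arrays alone, 351 with no filter, 266 without the variance trend and 294 with 1 probe set per gene. Median centring gave 319 higher and 323 lower.

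The mean of the 3 differences asked which genes differed on average over generations, with 6 arrays against 6. Fos rose by 2.49 ± 0.17 (n = 6 arrays per lineage; adjusted p = 1.63e-07), Fosb by 1.53 ± 0.20, Ier2 by 1.27 ± 0.09, Egr1 by 0.99 ± 0.10 and Ergic1 by 1.11 ± 0.07. The secretoglobins Scgb1d4, Scgb1d2 and Scgb2a1 rose by 1.88 ± 0.11, 1.77 ± 0.13 and 1.62 ± 0.16 on average, most of it from F3. Mbp rose by 1.13 ± 0.17 and Tpm3 (1387617_at) also rose, against other probe sets of both genes named above. Nedd4 (1395157_at) fell by 2.41 ± 0.07 (adjusted p = 2.13e-11), followed by Eprs1 (−2.28 ± 0.11), Scaf11 (−1.84 ± 0.12), Ccar1 (−1.70 ± 0.11) and Sf3b1 (−1.68 ± 0.10). Dag1, the dystroglycan gene, gave −1.62 ± 0.11 (1392391_at), Tbl1x −1.59 ± 0.18, Dhx36 −1.57 ± 0.09, Ipo5 −1.57 ± 0.12 and Ppp3r1 −1.56 ± 0.12. A pair of other Dag1 probe sets fell too (1389105_at, −1.56, and 1371430_at, −0.90), while 1371429_at gave 0.02. Ccar1 rose at 1376864_at (0.21), Scaf11 at 1397528_at (0.31) and Tbl1x at 1388478_at (0.15), against the falls above.

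**Figure D3:**
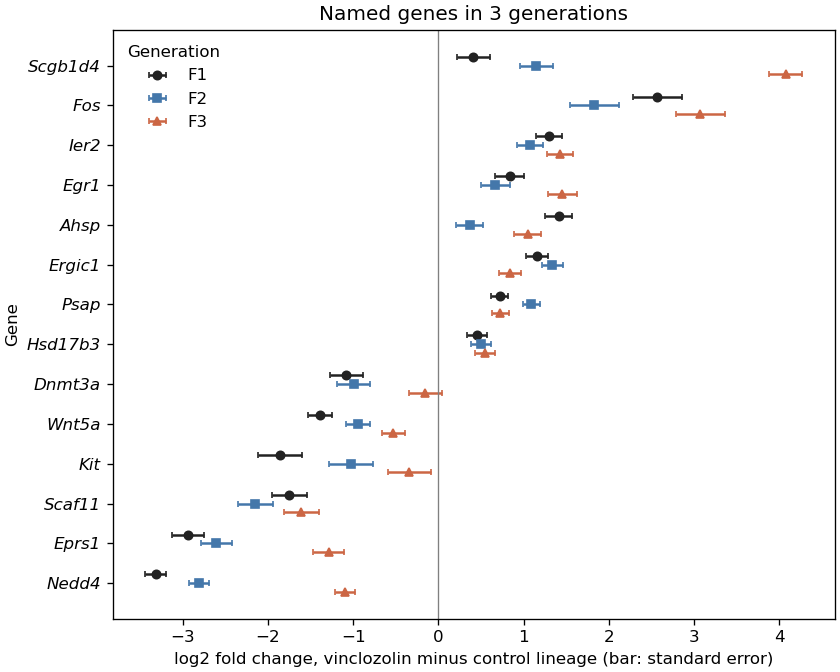
Log2 fold change, vinclozolin minus control, of 14 named genes in F1, F2 and F3, with bars of 1 SE from the fit (2 arrays per group). Fos lies between 1.83 and 3.07 in all 3 generations, Scgb1d4 rises to 4.08 in F3, and Nedd4 goes from −3.32 in F1 to −1.10 in F3.

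Oxidative phosphorylation genes were higher in 49 of 63 members in the mean and lower in 0 (50 adjusted over the list alone; median 0.27; adjusted p = 5.98e-15, and adjusted p = 0.390 with an estimated correlation). Ribosomal protein genes were higher in 37 of 42 and lower in 0 (38 over the list alone; median 0.25; adjusted p = 6.07e-15, and adjusted p = 0.390 with an estimated correlation), but were not called after quantile normalization (median 0.03, adjusted p = 0.471). Erythroid genes were higher in 8 of 16 and lower in 0, also over the list alone (median 0.22; adjusted p = 0.00194, and adjusted p = 0.390 with an estimated correlation). They were not called in F2 (median 0.00, adjusted p = 0.754). Interstitial and stromal genes were lower in 8 of 16 and higher in 3 (9 and 3 over the list alone; median −0.17; adjusted p = 0.0258, and adjusted p = 0.390 with an estimated correlation), with Wnt5a at −0.96 ± 0.08 and Tcf21, a regulator of gonadal mesenchyme, at −0.37 ± 0.06. That list was not called without F1 control replicate 1 (adjusted p = 0.0530). Germ cell genes were lower in 6 of 15 and higher in 0, also over the list alone (adjusted p = 0.0615), and chromatin regulators lower in 12 of 36 and higher in 4, also over the list alone (adjusted p = 0.0510). Chromatin and extracellular matrix genes (the latter adjusted p = 0.0534) were called lower after quantile normalization (both adjusted p = 0.00363) and cyclic loess (both adjusted p = 0.00428), and germ cell genes after median centring (adjusted p = 0.0488). With an estimated correlation none of these was called (adjusted p = 0.321 at the lowest). Not called in the mean were immediate early and heat shock genes (7 of 29 higher and 2 lower, also over the list alone, adjusted p = 0.321), Leydig cell genes (7 of 20 and 3, with 9 and 3 over the list alone, adjusted p = 0.321), Sertoli cell genes (6 of 16 and 1, with 6 and 2 over the list alone, adjusted p = 0.375) and androgen-responsive genes (4 of 15 and 2, also over the list alone, adjusted p = 0.846). The beta-actin ratio of the same arrays was 0.260 ± 0.097 (vinclozolin) against 0.453 ± 0.018 (control; SD, n = 6 each).

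**Figure D4:**
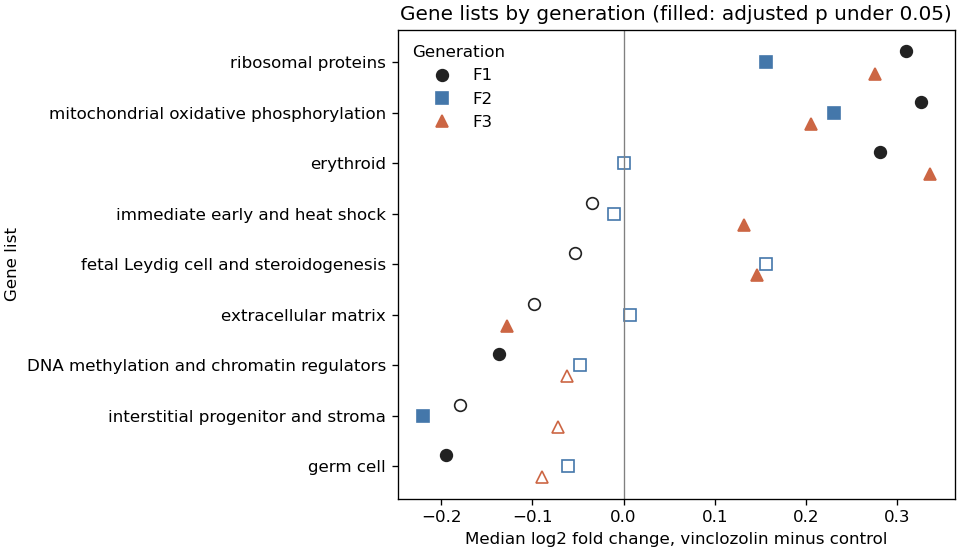
Median log2 fold change, vinclozolin minus control, of 9 gene lists in F1, F2 and F3, with filled symbols for an adjusted p under 0.05. Oxidative phosphorylation genes lie at 0.33, 0.23 and 0.21 and ribosomal protein genes at 0.31, 0.16 and 0.28, the latter falling to 0.06, 0.04 and 0.02 after quantile normalization.

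In the mean 7245 probe sets (33.3%, 4575 genes) were called, 3072 higher and 4173 lower. Directions were balanced after quantile normalization (3676 higher, 3601 lower) and turned after median centring (5524 higher, 2795 lower) and with 1 probe set per gene (1965 higher, 1506 lower of 3471). Median centring moved the median log2 fold change of all tested probe sets in F1 and F2 from −0.01 to 0.10 and 0.11. The beta-actin ratio of each array as a covariate was an alternative chosen after seeing the data. With it 404 probe sets were called for lineage, against 6132 in the same model without the ratio. The ratio itself was called for 1629 probe sets. Of the 7245 called in the mean, 325 were also called for lineage with the ratio. Ratio and lineage ran together over the arrays (r = −0.78). In that model Kit, Sox2, Dnmt3b, Tcf21 and Ndufa7 were not called and had the opposite sign (0.13, 0.40, 0.33, 0.03 and −0.03). The list of interstitial and stromal genes was not called for lineage there (median −0.11, adjusted p = 0.251). Germ cell genes had a lineage median of 0.02 (adjusted p = 0.734) and were called for the ratio (adjusted p = 0.0173). That ratio call was lost with an estimated correlation (adjusted p = 0.341). With the ratio, immediate early and heat shock, Leydig cell and erythroid genes were called higher for lineage (adjusted p = 9.11e-04, 0.00237 and 0.00237). Extracellular matrix genes were called lower (adjusted p = 0.0213), and the ribosomal and oxidative phosphorylation lists stayed called higher. None of these lineage calls held with an estimated correlation (adjusted p = 0.495 at the lowest). Without F1 the mean gave 4091.

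The lists of the 3 generations shared more probe sets than independent lists would. Each generation had its own control arrays, but the lists were not independent. The fit pooled the spread of a probe set over all groups, so one with a small spread is more easily called in each generation. The expected counts do not allow for this. The beta-actin ratio was also lower on the vinclozolin arrays in all 3 generations, and its share in the overlap was not tested. F1 and F2 shared 586 higher and 1503 lower probe sets (96.1 and 288 expected if independent), F1 and F3 shared 120 and 239 (21.5 and 61.5 expected), and F2 and F3 shared 93 and 265 (10.7 and 43.2 expected). Past the looser threshold in all 3 generations were 18 probe sets higher and 210 lower, 228 in all (0.06 and 3.76 expected). Among the higher were Fos, Fosb, Ier2, Ergic1, Psap (mean 0.85 ± 0.06), Metrn, a neurotrophic factor gene (0.86 ± 0.10), and Tpm3; among the lower were Nedd4, Eprs1, Scaf11, Ccar1 and Dag1. The count of 228 was 53 with an offset of 64. Fold changes correlated across probe sets with r = 0.71 between F1 and F2, 0.40 between F1 and F3 and 0.47 between F2 and F3 (rho = 0.62, 0.37 and 0.43), where probe sets are not independent replicates. The highest absolute r of the other relabellings of arrays within generations was 0.14, 0.18 and 0.15 (9 relabellings each, so no p under 0.05 was possible).

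The test of whether the difference depended on generation called 565 probe sets (2.60%). Scgb1d4 had the smallest p with Nedd4 (adjusted p = 3.63e-05 each), followed by Scgb1d2 (adjusted p = 3.02e-04), the exportin gene Xpo7 (1397747_at; −2.18, −0.93 and 0.02 in F1, F2 and F3; adjusted p = 0.00129) and Prrc2c (1378155_at; −0.40, −0.00 and 0.76; adjusted p = 0.00192). Another probe set of Prrc2c, 1399079_at, rose by 0.27 in F1. The count was 178 and 149 without F1 control replicates 1 and 2, 318 and 327 without F2 control replicates 1 and 2, 130 and 64 without F3 control replicates 1 and 2, 3506 and 980 without F1 vinclozolin replicates 1 and 2, and 120 and 251 without F3 vinclozolin replicates 1 and 2.

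Among the control groups of the 3 generations, limma called 0 of 21729 probe sets, with 517 at an unadjusted p under 0.05. That is fewer than chance alone gives at this threshold. The pooled spread included the vinclozolin replicates (SD 0.18 to 0.24, against 0.13 to 0.16 in control groups). The test was therefore conservative for controls and does not show that they were alike. The same pooling understates the spread of the F1 vinclozolin arrays. The smallest p was that of the adaptor protein gene Dok3 (8.29e-05, adjusted 1.00), followed by Il23a, Chst10, Csnk2a1 and Tmem185b. Dok3 and Il23a are among the genes called in F2 and F3, where their control signals were 3.25 and 6.5, against 28.0 and 35.5 in F1 controls. Control arrays of different generations correlated at 0.989 to 0.991 over probe sets, vinclozolin arrays of different generations at 0.959 to 0.983 (median 0.972) and arrays of different lineage at 0.947 to 0.982 (median 0.970).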

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

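Chosen only after the result was seen were the tests of opposite directions within genes, of splits for probe sets, all 3 tests on prostatein genes, the covariate test on ribosomal and oxidative phosphorylation genes and the reading of the planned quantile normalization as a test on ribosomal genes, as was cyclic loess; the tests on replicate pairs, splits for gene lists and matched random lists for oxidative phosphorylation were set beforehand.

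The difference between lineages depended on generation, by a test of that difference, for 565 probe sets (64 to 3506 with 1 array left out; lowest without F3 control replicate 2, highest without F1 vinclozolin replicate 1). It was 178 and 149 without F1 control replicates 1 and 2, 318 and 327 without F2 control replicates 1 and 2, 130 without F3 control replicate 1, 980 without F1 vinclozolin replicate 2, and 120 and 251 without F3 vinclozolin replicates 1 and 2. Scgb1d4 and Nedd4 (both adjusted p = 3.63e-05), Scgb1d2 (adjusted p = 3.02e-04), Xpo7 (adjusted p = 0.00129) and Prrc2c (adjusted p = 0.00192) had the smallest p. Gene lists were compared in the same way between generations. The values are medians, over the members of a list, of the difference in log2 fold change of each gene, not changes of the list's median. From F1 to F2 this was 0.12 for Leydig cell genes, −0.31 for erythroid, −0.12 for oxidative phosphorylation and −0.14 for ribosomal protein genes (adjusted p = 0.0265, 0.00356, 4.59e-05 and 2.23e-06). From F1 to F3 it was 0.26 for germ cell, 0.14 for Leydig cell, 0.38 for immediate early and heat shock and −0.16 for oxidative phosphorylation genes (adjusted p = 0.0328, 0.0226, 0.0165 and 0.0165). From F2 to F3 it was 0.41 for erythroid, −0.19 for extracellular matrix, 0.17 for immediate early and heat shock and 0.11 for ribosomal protein genes (adjusted p = 3.01e-04, 0.00171, 0.00269 and 0.00129). Those of ribosomal protein genes were not called after quantile normalization (−0.01 from F1 to F2, adjusted p = 0.831; −0.03 from F2 to F3, adjusted p = 0.852) or cyclic loess (adjusted p = 0.593 and 0.905), nor those of oxidative phosphorylation and germ cell genes after quantile normalization (adjusted p = 0.0582 from F1 to F2, and 0.0807 and 0.0502 from F1 to F3). Extracellular matrix genes were called from F1 to F2 after quantile normalization only (adjusted p = 0.0453, and adjusted p = 0.783 with an estimated correlation). On the deposited scale none of the 12 differences was called with an estimated correlation (adjusted p = 0.440 at the lowest and 0.929 at the highest).

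Signals that differed between lineages were also present in probe sets left out of the tests. Among the control probe sets, vinclozolin minus control arrays differed by −0.193 in the beta-actin 5' to 3' ratio, −0.216 in its middle to 3' ratio, −0.173 in the Gapdh 5' to 3' ratio and 107 in the mean spike-in signal (685 against 578). The spike-in means of vinclozolin and control arrays were 752 and 494 in F1, 636 and 636 in F2, and 667 and 604 in F3, so F2 did not show the difference. The exact permutation p (2-sided, n = 6 each) was 0.00216, 0.00216, 0.0411 and 0.0195, and 0.00361, 0.00361, 0.0411 and 0.0244 after adjustment over 5 measures. Among dim probe sets, 3 of the 4 for Andpro (1367558_x_at, 1371364_a_at and 1388302_x_at) had mean signals of 55.8, 52.4 and 38.8 on the F3 vinclozolin arrays, and Sbp had 88.2. The highest control arrays gave 0.3, 0.7, 1.8 and 7.1.

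The lineage difference over all tested probe sets came with lower 5' signal, and a loss of 5' signal in the vinclozolin RNA pools is a candidate explanation. Of 100 splits drawn from 108 exchanges of lineage within generations, 1, the real one, gave as many as 7245 probe sets (highest other 3832). Chance is an unlikely cause for the probe sets only if the arrays of a group are independent pools. Shared litters or hybridisation days within a group, which the labels do not give, could put the real split first without an effect of lineage. For the 4 gene lists called, 28 of 100 splits gave as many (highest other 8), so chance cannot be excluded for the lists. Pairs of probe sets of 1 gene that were both called in F1 went in opposite directions in 39.9% (169 of 424, against 47.9% if independent). A 5' loss could give such pairs if they lie at different distances from the 3' end, which was not measured. Probe sets that vary independently would give opposite directions too, so this share cannot decide. Within the 6 replicate pairs the slope on the log2 ratio was −0.497 (exact 1-sided sign-flip p = 0.0625, 64 flips), and ratio and lineage ran together over the arrays (r = −0.78), so the share of 5' loss and of a biological lineage difference, which stays open and untested, cannot be told apart.

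The prostatein genes Scgb1d4, Scgb1d2 and Scgb2a1 were high on both F3 vinclozolin arrays (239 and 288, 208 and 249, and 167 and 214), and on the F1 and F2 vinclozolin arrays they lay at 9.8 to 26.4, above each control array for the same gene (at most 9.3, 5.2 and 7.0). A loss of 5' signal that follows the beta-actin ratio would give the smallest differences in F3, where that ratio had fallen least. The F test over all 21729 probe sets called a dependence on generation for each of the 3 (adjusted p at most 0.00230), with the highest signals in F3. The 3 genes were taken up because they were the highest in F3. That order was thus fixed by the choice and cannot decide on such a loss. The size of the signals argues against it as the cause for these 3 genes. A loss lowers signal, yet all 3 rose on both F3 vinclozolin arrays, to 167 or more (at most 9.3 on control arrays). The Gapdh ratio was not lower there (0.996 ± 0.038 against 0.965 ± 0.008 on F3 controls, SD, n = 2 each), though the beta-actin ratio was (0.378 against 0.453). RNA of adult ventral prostate may be in the F3 pools, where Sbp and 3 Andpro probe sets gave 33.2 to 94.3 on both arrays against at most 11.2 elsewhere, under the limit of 14.8 below which probe sets were left out, so no fold is given. This stays open, since no prostate RNA was measured for comparison and the signals in F1 and F2 were too near that limit to compare. The remaining Andpro probe set (ratio 0.196) lay under the limit on all arrays and cannot decide. Genes of other prostate lobes and accessory glands (Pbsn, Msmb, Tgm4, Svs4) gave at most 17.9 on the F3 vinclozolin arrays. They do not bear on RNA of the ventral lobe. A response of the testis to androgen stays open too, since the list of androgen-responsive genes, whose tested members hold none of the prostate genes, had an adjusted p of 0.951 in F3, as does a biological difference between lineages, which was not tested.

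Ribosomal protein and oxidative phosphorylation genes were higher in the mean of the generations. The median of oxidative phosphorylation genes, 0.27, lay at percentile 100 of 10000 random lists matched on expression (random median 0.11, highest 0.21). The random genes were drawn singly, so correlation between members was not allowed for. The percentile alone therefore cannot decide on a trend with mean expression. After quantile normalization the median was 0.19 (adjusted p = 2.68e-08, and adjusted p = 0.398 with an estimated correlation). For ribosomal protein genes the percentile was 99.98, but their median of 0.25 dropped to 0.03 after quantile normalization (adjusted p = 0.471) and to 0.07 after cyclic loess (adjusted p = 0.00554), against 0.35 after median centring (adjusted p = 8.72e-13), so such a trend cannot be told apart from a rise, as the scalings keep it open. With the beta-actin ratio in the model both lists stayed called for lineage (adjusted p at most 1.94e-04). The lineage medians were 0.17 for ribosomal and 0.11 for oxidative phosphorylation genes. Both lists were called for the ratio too (adjusted p = 0.0173 and 1.57e-05). With an estimated correlation neither the lineage calls (adjusted p = 0.569 and 0.617) nor the ratio calls (adjusted p = 0.811 and 0.699) held. In the mean without the ratio, the adjusted p with an estimated correlation was 0.390 for both. A loss of 5' signal as the whole cause therefore cannot be told apart, as the correlation between genes keeps it open, from a biological lineage difference, which stays open and untested.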

How the results depend on the processing

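Cyclic loess normalization, the beta-actin ratio as a covariate and leaving a generation out of the mean were chosen only after the result was seen; the other alternatives were planned. Of the 349 gene results named past the threshold (191 genes), 322 kept direction and call after quantile normalization, 316 after median centring, 323 after cyclic loess, 325 of 335 with an offset of 1, 298 with no filter and 277 to 343 with 1 array left out. All 284 whose probe sets lay above the lowest 50% of signals kept both when the rest were left out, and no filter was the setting that brought in signals near background. A reversed direction occurred only with the beta-actin ratio as a covariate, where 22 of 109 results in the mean kept their call, 71 lost it and 16 changed sign with adjusted p = 0.324 to 0.987: Kit 0.13, Sox2 0.40, Fgf9 −0.0297, Tcf21 0.0267, Sox18 0.0216, Tnnc1 −0.0553, Erbb3 0.0112, Dnmt3b 0.33, Tnfrsf1a 0.0595, Casp6 0.0654, Timp1 −0.0191, Arnt 0.11, Pgk1 −0.16, Ndufa7 −0.0310, Rdh10 0.0874 and Rara 0.0146. The same model gave 404 probe sets in the mean, as the median SE rose from 0.0978 to 0.174 and the median size of the called changes went from 0.34 to 0.20.

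With no filter, F3 gave 351 probe sets, the dependence on generation 313, the mean 7 gene lists and the correlation of F1 with F2 0.61. The looser threshold gave 53 probe sets with an offset of 64 and 1125 with a fold of 1.2. Without the variance trend F3 gave 266 and the dependence on generation 129. Array weights gave 3319 in F1, 2712 in F3 and 942 for the dependence on generation. Cyclic loess gave 8 lists in F1 and 8 in the mean, and the mean of the probe sets of a gene gave 7 in the mean. The 4 arrays of the generation alone gave 2294 in F1 and 2262 in F3. With 1 probe set per gene the counts were 2190, 1072, 294, 3471 (mean) and 82 (dependence on generation) of 11293 features. An adjusted p under 0.1 gave 1423 in F3 and 1071 for the dependence on generation, as a looser threshold must. An estimated correlation left 0, 0, 0 and 0 gene lists in F1, F2, F3 and the mean, against 5, 3, 6 and 4. Leaving F1 out of the mean gave 4091. Where no reason is given the cause was not tested.

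With each array left out in turn, where the remaining array of that group was taken to vary like the others, the counts ran from 2514 to 7183 (F1), 1083 to 4884 (F2), 65 to 2172 (F3), 5650 to 8854 (mean), 64 to 3506 (dependence on generation), 0 to 0 (control generations) and 192 to 280 (looser threshold). Gene lists ran from 2 to 6 in F1, 3 to 3 in F2, 5 to 6 in F3 and 3 to 7 in the mean, which gave 7 without F3 control replicate 2, F1 vinclozolin replicate 1 or F3 vinclozolin replicate 1. Correlations ran from 0.62 to 0.71, 0.32 to 0.41 and 0.40 to 0.48. Replicate numbers did not pair arrays across groups (deviations of equal numbers correlated at −0.09 to 0.07 over 15 pairs of groups). With the number as a block, F1, F2, F3 and the mean gave 5009, 3117, 713 and 7189, and with a block within each generation the mean gave 7019. Control generations gave 0 by limma under each alternative run for them (517 at an unadjusted p under 0.05).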

Other observations

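Cyclic loess normalization was chosen only after the result was seen; the gene lists and their tests were fixed beforehand. The gene lists left out of the report were not called in F1, F2, F3 or the mean on the deposited scale, and counts of members adjusted over the list alone are given where they differ. Xenobiotic metabolism had 4 of 24 genes higher and 4 lower in F1, 2 and 1 in F2, 2 and 0 in F3 and 5 and 3 in the mean (5 and 4 in F1, 3 and 0 in F3, and 5 and 5 in the mean adjusted over the list alone; adjusted p = 0.888, 0.936, 0.163 and 0.792). The glutathione transferase gene Gsta4 rose by 0.40 ± 0.09, 0.73 ± 0.09 and 0.64 ± 0.09 in F1, F2 and F3 (n = 2 arrays per group). Gstm2, another glutathione transferase gene, stood at −0.73 ± 0.11 in F1 and −0.51 ± 0.11 in F2. Hypoxia and glycolysis had 4 of 33 higher and 4 lower in F1, 1 and 2 in F2, 0 and 1 in F3 and 5 and 6 in the mean (adjusted p = 0.428, 0.554, 0.141 and 0.244), with the phosphofructokinase gene Pfkl at −0.45 ± 0.13, −0.57 ± 0.13 and −0.66 ± 0.13. This list was called lower in F3 after quantile normalization (adjusted p = 0.0285) and in F3 and the mean after cyclic loess (adjusted p = 0.0126 and 0.0282), and not with an estimated correlation (adjusted p = 0.294, 0.317 and 0.329). Imprinted genes had 2 of 24 higher and 4 lower in F1, 1 and 3 in F2, 0 and 1 in F3 and 3 and 6 in the mean (0 and 4 in F3 adjusted over the list alone; adjusted p = 0.327, 0.417, 0.209 and 0.182). They were called lower in F1, F3 and the mean after quantile normalization (adjusted p = 0.0230, 0.0117 and 0.00564) and cyclic loess (adjusted p = 0.0234, 0.00990 and 0.00497). With an estimated correlation these were not called (adjusted p = 0.216, 0.226 and 0.154, and 0.243, 0.268 and 0.153). Among them Plagl1 stood at −0.69 ± 0.15 in F1 and −0.51 ± 0.15 in F2, and Meg3 rose by 0.73 ± 0.15 in F2.

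Peritubular myoid and smooth muscle genes had 1 of 14 higher and 1 lower in F1, 2 and 2 in F2, 0 and 2 in F3 and 1 and 2 in the mean (1 and 2 in F3 adjusted over the list alone; adjusted p = 0.770, 0.845, 0.254 and 0.530). Acta2, the smooth muscle actin of myoid cells, was lower in all 3 generations (−0.69 ± 0.10, −0.79 ± 0.10 and −0.55 ± 0.10). Endothelial genes had 1 of 18 higher and 4 lower in F1, 1 and 2 in F2, 0 and 0 in F3 and 2 and 4 in the mean (adjusted p = 0.283, 0.536, 0.298 and 0.182), with Sox17 lower (−0.69 ± 0.17 and −0.70 ± 0.17) and the tight junction gene Cldn5 higher (0.48 ± 0.11 and 0.39 ± 0.11) in F1 and F2. Growth factor genes of cord formation had 4 of 25 higher and 3 lower in F1, 1 and 3 in F2, 0 and 2 in F3 and 2 and 7 in the mean (5 and 4 in F1 and 0 and 3 in F3 adjusted over the list alone; adjusted p = 0.770, 0.603, 0.116 and 0.375). The insulin receptor gene Insr stood at −0.83 ± 0.20 in F1 and −0.93 ± 0.20 in F2. Retinoic acid genes had 2 of 15 higher and 2 lower in F1, 0 in F2 and F3 and 2 and 3 in the mean (1 and 0 in F3 and 2 and 4 in the mean adjusted over the list alone; adjusted p = 0.537, 0.845, 0.951 and 0.588), with Rdh10 at −0.92 ± 0.14 in F1. Cholesterol genes had 1 of 19 higher and 2 lower in F1 and in F2, 0 in F3 and 3 and 5 in the mean (2 and 1 in F3 and 4 and 5 in the mean adjusted over the list alone; adjusted p = 0.308, 0.634, 0.951 and 0.530). Apoptosis and p53 genes had 0 of 28 higher and 4 lower in F1, 0 and 3 in F2, 0 in F3 and 2 and 4 in the mean (0 in F2 adjusted over the list alone; adjusted p = 0.308, 0.232, 0.951 and 0.244). Cell cycle genes had 1 of 41 higher and 4 lower in F2, 0 in F3 and 4 and 5 in the mean (1 and 3 in F3 and 4 and 4 in the mean adjusted over the list alone; adjusted p = 0.936, 0.794 and 0.698), with the cyclin gene Ccne2 at −0.69 ± 0.12 in F2.

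Genes of neighbouring tissues were followed as well. Macrophage and leukocyte genes had 0 of 20 called in each generation and 1 lower in the mean (0 adjusted over the list alone; adjusted p = 0.438, 0.205, 0.951 and 0.244). Mesonephros and duct genes had 1 of 11 lower in F1, 0 in F2 and F3 and 2 lower in the mean (1 higher and 1 lower in F3 adjusted over the list alone; adjusted p = 0.308, 0.845, 0.669 and 0.375), with Pax8 at −1.07 ± 0.29 in F1. Skeletal muscle genes had 2 of 13 higher and 1 lower in F1, 0 and 1 in F2, 0 in F3 and 2 and 1 in the mean (0 and 1 in F3 adjusted over the list alone; adjusted p = 0.649, 0.869, 0.951 and 0.892). Nerve genes had 0 of 15 higher and 2 lower in F1, 0 and 1 in F2, 0 in F3 and 2 and 2 in the mean (1 and 0 in F3 adjusted over the list alone; adjusted p = 0.649, 0.569, 0.951 and 0.530). Erbb3, a Schwann cell receptor gene, stood at −1.04 ± 0.18 in F1 and −0.83 ± 0.18 in F2. Ovary genes had 0 of 10 called in F1, F2, F3 and the mean (adjusted p = 0.649, 0.845, 0.669 and 0.546). Of the adrenal list 3 genes were tested, too few for a list: Mrap rose by 0.48 ± 0.14 in the mean (adjusted p = 0.0143), and Ddc and Akr1b7 were not called (adjusted p = 0.262 and 0.362). Of the sex-linked genes 2 were tested, and both Y-linked genes were lower in the mean (Uty −0.31 ± 0.06, adjusted p = 0.00189; Eif2s3y −0.34 ± 0.09, adjusted p = 0.0110).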
